A study of Glycine max with 2 samples.

How the data were processed

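Leaves of greenhouse-grown soybean were frozen in liquid nitrogen, RNA was isolated with a Genall Ribospin kit and libraries were sequenced on an Illumina NovaSeq, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36 and compared with DESeq 1.36.0, per the submitters' processing notes. The aligner, read counter, genome build and annotation are not given in the sources used here. The series has 2 samples, 1 per age (50 and 95 days after sowing), and each is a comparison of 2 libraries, so there is 1 library per type and age. Per the file headers, each deposited table gives a transcript identifier, a symbol, an Arabidopsis match, a description, a value for A and for B, a log2 ratio, a p-value and an adjusted p-value.

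The deposited values for A and B are a signal that is never negative. In each of the 4 columns, every value minus 1 was a whole multiple of 1 step within 0.01 of a whole number, for 100% of values. A column was therefore taken as 1 library's whole-number counts divided by a size factor, with 1 added. These counts are called reads here. Whether they are reads counted directly or rounded estimates per isoform is not known, since the counter is not given. The size factors implied are 1.25 for A and 1.06 for B at 50 days, and 0.803 for A and 0.914 for B at 95 days. Their product was 1.33 at 50 days, 0.734 at 95 days and 0.974 over all 4, from which joint scaling of the 4 libraries was inferred; no source states it. The log2 ratio in the deposited tables equals the log2 of B over A with the added 1 included, to within 7.47e-07, and was used as the authors' log2 value. The p-values and adjusted p-values are the authors' deposited ones; from their ratio, about 62413 transcripts were tested at 50 days and 59955 at 95 days. Because each table lists only p-values under 0.05 (highest 0.04997 and 0.04998), its columns' sums are not library depths, and the depth of the libraries is unknown. The precision of a value is set by its own reads.

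Normalised reads are given as the deposited value minus 1. Where the lower library had no read, the fold is a lower bound against 3 reads; otherwise it is the ratio with a 95% Clopper-Pearson interval on the reads. At 50 days 1 row was an exact repeat and was counted once. Transcripts were called at the authors' adjusted p under 0.05 with an absolute log2 ratio of at least 1. Names come from the tables; the RefSeq table supplied for soybean held no matching locus names and was not used, and no coordinates are given.

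The calling rule, 30 gene lists defined by words in the symbol, match and description, and the rule for named transcripts were fixed before the data were examined. That rule takes, per age, up to 8 called transcripts per side by log2 ratio with a name and at least the median level of called ones, up to 8 called clock members, from each other list with at least 3 called members 2 of the majority and 1 of the other side, up to 10 called at both ages and up to 6 of opposite direction. Only 4 named transcripts passed on the A side at 95 days. Other transcripts and subgroups named in the text were chosen after their values were seen, as examples of the fixed lists. A list of at least 5 listed members was described by its split and by the percentile of its median among 10000 random lists of the same size drawn from the same table in 5 bins of mean level. The percentile of its share in A among such lists was added after seeing the data. Adjusting over a list alone was not possible, since p-values of unlisted members are not in the tables used. The planned Fisher's exact tests on lists were also computed, but transcripts are not replicates and no p is reported from them. Of 59 list and age pairs tested for side among listed transcripts, 4 passed after Benjamini-Hochberg adjustment, the clock, cytokinin, phenylpropanoid and cell division lists at 50 days. None passed in the other families of these tests, 0 of 59 for calls in A against the rest, 0 of 59 for calls in B and 0 of 13 for side among called transcripts.

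The steps were tested on simulated data, with 500 random lists each and for the median only. At 50 days, with 2413 transcripts, lists of 30 with 27 placed in A fell below percentile 2.5 in 77.5% of 40 lists, and random lists fell outside percentiles 2.5 to 97.5 in 7.5%. At 95 days, with 2471 transcripts, these were 97.5% and 5%. The simulated ratios were shuffled over transcripts, so isoforms of one gene were no longer alike. These rates therefore do not cover lists with many isoforms per gene, such as the clock and cytokinin lists. Alternatives covered the p threshold, the minimum fold, filters on level and on 0 reads, centring, the pseudocount, list membership and scaling between ages; counting 1 transcript per gene, or every listed transcript, was added after seeing the data. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.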

Results

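Leaf RNA of soybean (Glycine max) was sequenced from plants of an early and a late senescence type grown in a greenhouse, at 50 and at 95 days after sowing. The study asked which genes differ in expression between the types at each age, and its title names the circadian clock. Each age was represented by 1 table made by the authors, which compares 2 libraries, called A and B there. Neither the column headers nor the labels say which of them is the early type, and nothing states that A at 50 days and A at 95 days are the same type. The libraries are therefore called type A and type B throughout. With 1 library per type and age there was no replicate, so no difference below has a replicate check and the authors' p-values compare 2 libraries, not the types.

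Each table lists transcripts (isoforms of a gene model) and not genes. At 50 days it held 2413 different transcripts of 2085 genes, of which 1468 had more normalised reads in A and 945 in B. At 95 days it held 2471 transcripts of 2126 genes, 1154 with more in A and 1317 with more in B. All had an unadjusted p under 0.05 in the authors' deposited table, so transcripts that did not differ are not represented and library totals could not be had. For the same reason a fold is that of a single isoform, and the gene's total over all its isoforms is not known. A transcript is called below where the authors' adjusted p is under 0.05 and the absolute log2 ratio at least 1. There were 112 called transcripts at 50 days, 77 higher in A and 35 higher in B, and 37 at 95 days, 19 higher in A and 18 higher in B. In 104 of the 112 and 32 of the 37, the other library had no read. Folds against 0 reads are given as lower bounds, computed against 3 reads per library, and other folds with a 95% interval from the exact (Clopper-Pearson) binomial. Intervals and bounds cover counting error only, and take the whole-number values as reads counted directly, which could not be checked.

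At 50 days, clock transcripts were mostly on the A side. Of 42 listed transcripts of the circadian clock list, 37 had more reads in A and 5 in B, and the 4 called ones were all higher in A. The leading one was Glyma.06G136600.1, a PRR95-like pseudo-response regulator, a family of repressors within the plant clock, with 14611 normalised reads in A and none in B, at least 5187-fold higher. Its adjusted p was 0.00944 in the authors' deposited table. Glyma.07G049400.14, a second PRR95-like gene, was at least 368-fold higher in A. Glyma.19G260900.1, an LHY transcript, encoding a morning-expressed MYB factor of the clock, was at least 378-fold higher in A. Glyma.09G167900.1, a REVEILLE 7-like MYB factor, had 3838 normalised reads in A and 4.69 in B, 818-fold higher (350 to 2519). More-read isoforms of the last genes named, Glyma.07G049400.16, Glyma.19G260900.2 and Glyma.09G167900.2, also lay in A but were not called. Their deposited log2 ratios of B over A were smaller in size, -7.27, -5.14 and -4.998. Those of the called isoforms were -10.02, -10.06 and -9.40. All 22 listed PRR5, PRR7 and PRR9-like transcripts, from 6 genes, and all 7 LHY-like transcripts had more reads in A. GIGANTEA, Glyma.10G221500.1, had 4334 against 9.39. The 5 clock transcripts with more reads in B were the 2 listed of TOC1 (APRR1), the 2 of REVEILLE 1 and 1 of 2 EARLY FLOWERING 3-like ones, the other, Glyma.07G013500.2, having 523 in A and none in B. TOC1-like Glyma.17G102200.4 had 1574 in B and 51.4 in A, 30.6-fold (23.9 to 39.97), and REVEILLE 1, Glyma.02G241000.1, had 1182 in B and 36.9 in A. The median log2 ratio of B over A in the clock list was -8.04 (-7.47 with 0 reads set to the bound), at percentile 0.13 of 10000 random lists matched on level. Percentiles beside a split are those of the list's median, low ones lying towards A, unless the share in A is named. The clock list's share in A was at percentile 100. With 1 transcript per gene the split was 15 in A and 5 in B, the median at percentile 19.9 and the share at 87.3, so the list's distance from random lists rested on genes with many isoforms.

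**Figure D1:**
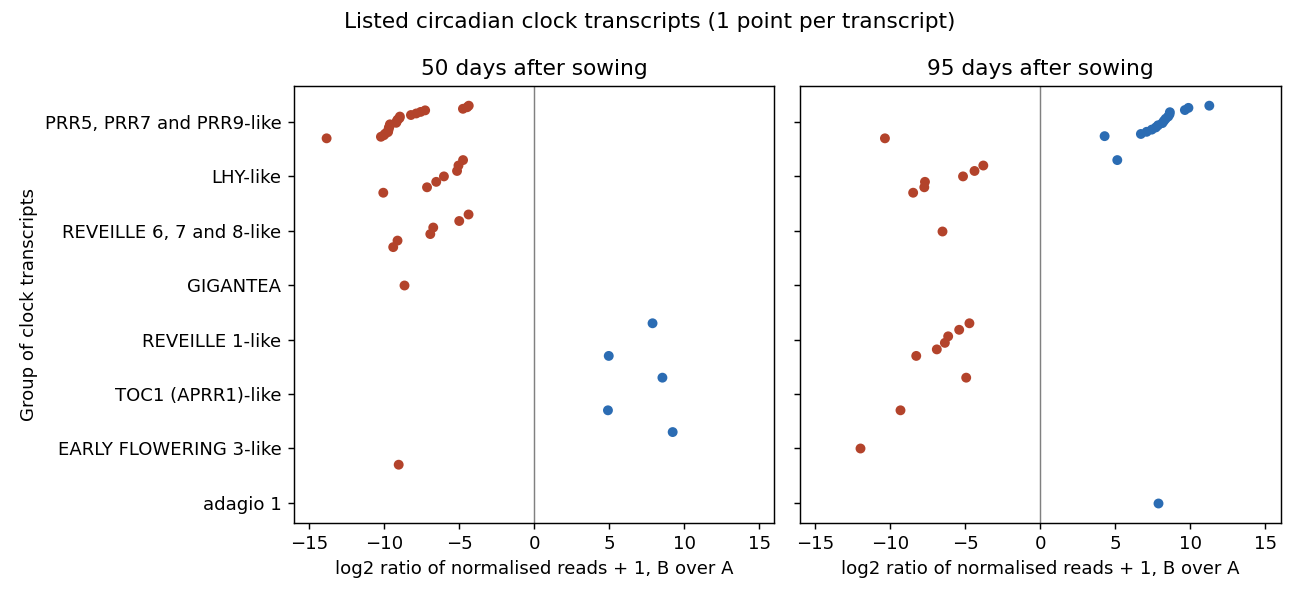
Log2 ratio of normalised reads plus 1, type B over type A, for each listed circadian clock transcript at 50 days (left) and 95 days (right), 1 point per transcript from 1 library per type, grouped by gene family; red points have more reads in A and blue points more in B. At 50 days all 22 PRR5, PRR7 and PRR9-like transcripts lie left of 0, and at 95 days 15 of 16 lie right of 0; values near 0 are missing because the tables hold only transcripts with an unadjusted p under 0.05.

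Phenylpropanoid and isoflavonoid transcripts also lay mainly on the A side at 50 days. Of 27 listed transcripts, each from a different gene, 24 had more reads in A and 3 in B, at percentile 0.28 of random lists, with a median log2 ratio of -7.29 (-5.79 with 0 reads at the bound). The 1 called member was Glyma.08G220200.3, a shikimate O-hydroxycinnamoyltransferase of the lignin pathway, at least 262-fold higher in A. All 6 dirigent proteins, all 4 isoflavone reductases and all 3 chalcone synthases listed had more reads in A, while laccases, which oxidise lignin precursors, divided 3 in A and 2 in B; these subgroups were singled out after their values were seen. Isoflavone reductase-like Glyma.11G070600.1 had 4792 normalised reads in A and 29.1 in B, 165-fold (116 to 243). Chalcone synthase 7, Glyma.01G228700.1, the entry enzyme of flavonoid synthesis, had 1312 against 73.2, 17.9-fold (14.3 to 22.8). Glyma.20G241700.1, chalcone isomerase 2-A, was among the 3 on the other side, with 24.1 in A and 820 in B.

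Cell division and histone transcripts lay mainly on the B side at 50 days. Of 40 listed transcripts of 38 genes, 29 had more reads in B and 11 in A, at percentile 99.0 of random lists, with a median log2 ratio of 5.61 (5.65 with 0 reads at the bound). Of the histone transcripts, 9 of 10 had more reads in B, including all 6 of histone H3.2, which packages newly replicated DNA. Histone H2AX, Glyma.03G148100.1, had 1231 in B and 20.1 in A, 61.3-fold (41.4 to 95.2). Histone copies are near-identical in sequence, and how the authors' counting divided reads among them is not given in the sources used here. Kinesins, the motor proteins of microtubules, went both ways, 13 in B and 8 in A. The 1 called member was Glyma.11G110800.5, a NACK1-like kinesin needed for cytokinesis, at least 491-fold higher in B.

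The called transcripts with the highest ratios at 50 days included isoforms of several enzymes of metabolism. Each fold is of the isoform named, and unlisted isoforms of its gene are missing, so the gene's total may not differ likewise. On the A side, Glyma.11G116600.3 and Glyma.11G116600.2, the large subunit of ADP-glucose pyrophosphorylase, which makes the precursor of starch, were at least 6318-fold and 4162-fold higher, and a second gene of it, Glyma.12G042400.2, at least 2872-fold. An ABC transporter of the G family, Glyma.08G070800.2, was at least 10570-fold higher in A. Also on that side were a CCCH zinc finger protein, Glyma.12G237300.2 (at least 2544-fold), a DUF3-like protein described as mucin-17, Glyma.11G033600.7 (3663-fold), and a protein kinase, Glyma.12G062900.4 (1776-fold). On the B side stood ribosomal protein L4, Glyma.10G048600.2, at least 4415-fold higher, and 2 enzymes of cuticular wax synthesis, LACS1, Glyma.03G221400.2 (at least 2707-fold), and CER1, Glyma.03G101800.1 (at least 2328-fold). Pectin acetylesterase 10, Glyma.13G117000.1 (1397-fold), polyphenol oxidase, Glyma.13G183500.1 (1470-fold), a mitochondrial phosphate transporter, Glyma.19G101100.1 (1479-fold), a CNOT4-like protein, Glyma.10G048700.5 (1212-fold), and a TMV resistance-like protein, Glyma.06G267400.4 (1511-fold), were also higher in B, these folds being lower bounds too.

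The salicylate and defence list divided 29 in A and 16 in B at 50 days, at percentile 52.5 of random lists, and all 4 called members were higher in A. That depends on the list's wording, since of 2 called TMV resistance-like transcripts outside it, Glyma.16G213700.1 was higher in A and Glyma.06G267400.4 in B. Among the 4 were resistance proteins Glyma.05G165800.2, at least 645-fold higher, and Glyma.03G047700.1, at least 482-fold. Another isoform of the first, Glyma.05G165800.1, had 1441 normalised reads in B and none in A. A pathogenesis-related protein 1-like transcript, Glyma.15G062400.1, had 2673 in A and 15.96 in B. Sugar transport and starch divided 13 in A and 5 in B, at percentile 30.3, with the sugar exporter SWEET20, Glyma.08G009900.1, called in A (at least 603-fold) and sucrose synthase, Glyma.09G073600.3, called in B (at least 660-fold). Chlorophyllide a oxygenase, which makes chlorophyll b, was called in A as Glyma.14G150600.1, at least 1515-fold higher. The 33 listed transcripts of the cytokinin list divided 30 in A and 3 in B, at percentile 0.58, but 24 of them also matched another list, mostly as pseudo-response regulators of the clock, and with 1 transcript per gene the percentile was 22.7.

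Lists closest to senescence held few listed transcripts at 50 days, and the only called one was in the abscisic acid list. All 4 NAC and all 5 WRKY factors had more reads in A, as did 2 of 3 transcripts of chlorophyll breakdown, each a pheophytinase. Of all listed transcripts at this age, 60.8% lay in A. The WRKY list, from 4 genes, had its median at percentile 26.8 and its share in A at 95.96, both within percentiles 2.5 and 97.5. Senescence proteases divided 3 in A and 6 in B, at percentile 93.7, autophagy 1 and 1, nitrogen remobilisation 9 and 4 (percentile 45.9), ethylene 8 and 5 (43.5) and jasmonate and storage proteins 2 and 5 (96.0). The abscisic acid list divided 8 and 9 (84.5), that one being a protein phosphatase 2C, Glyma.03G046800.1, higher in B. The medians of the remaining lists at 50 days were within percentiles 2.5 and 97.5, or the list had fewer than 5 members. In A and B they held 9 and 6 for flowering, 4 and 1 for light harvesting, 2 and 2 for carbon fixation, 3 and 1 for chlorophyll synthesis, 10 and 3 for auxin, 2 and 1 for gibberellin, 6 and 6 for heat shock, 5 and 10 for oxidative stress, 8 and 14 for cell wall, 1 and 4 for ribosomal proteins, 3 and 4 for guard cell, 1 and 2 for vascular tissue, 18 and 4 for seed proteins and 1 and 2 for nodule and root. By the share in A, 3 of these lists fell outside those bounds, cell wall at percentile 0.825 (0.91 with 1 transcript per gene) and oxidative stress at 1.235 (2.055), both towards B, and seed proteins at 97.955 (97.68), towards A. Of the seed list, 12 on the A side were lectin receptor kinases, which are not seed proteins. No transcript of the organelle and RNA quality list was listed at 50 days. Besides chlorophyllide a oxygenase, pectin acetylesterase 10 and ribosomal protein L4, these lists held 1 called transcript, a CONSTANS-LIKE 1-like factor of the photoperiod response, Glyma.13G303700.1, at least 303-fold higher in A.

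At 95 days the clock list was evenly divided, 17 transcripts in A and 17 in B, at percentile 36.0 of random lists, but its families were not. Of 16 PRR5, PRR7 and PRR9-like transcripts, 15 had more reads in B. The called member of the list was one of these, an APRR7 transcript, Glyma.13G135900.2, with 2446 normalised reads in B and none in A, at least 655-fold higher. The exception was another isoform of that gene, Glyma.13G135900.3, with 1309 in A and none in B. All 6 REVEILLE 1-like and 6 of 7 LHY-like transcripts had more reads in A. TOC1-like Glyma.17G102200.4 had 7993 in A and 259 in B, 30.8-fold (27.1 to 35.2), and EARLY FLOWERING 3-like Glyma.04G050200.3 had 4182 in A and none in B, at least 1274-fold.

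Called transcripts with the highest ratios at 95 days included, on the B side, THIC, Glyma.18G065700.2, an enzyme of thiamine synthesis, with 31020 normalised reads and none in A, at least 8302-fold higher. The snakin-like peptide peamaclein, Glyma.06G044400.1, had 29332 in B and 6.23 in A, 4710-fold (2018 to 14508). BRUTUS, Glyma.09G115100.3, a ubiquitin ligase of iron homeostasis, was at least 4267-fold higher in B, a plastid-lipid-associated protein, Glyma.06G127700.4, at least 3591-fold, a cold-regulated protein, Glyma.12G047500.2, at least 2597-fold, and an RNA-binding protein, Glyma.20G082800.3, at least 939-fold. On the A side were the DUF3-like Glyma.11G033600.7 (at least 1748-fold), the kinase SIS8, Glyma.08G165800.2 (2525-fold), the blue-light receptor phototropin 1, Glyma.12G074100.2 (1580-fold), and ferritin, Glyma.02G262500.2, an iron store of plastids (912-fold), each a lower bound. Here too the folds are of single isoforms and not of the genes' totals.

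No list other than clock and cytokinin held a called transcript at 95 days. The cytokinin list divided 6 in A and 17 in B, at percentile 98.2, with 18 members shared with another list and percentile 84.5 with 1 transcript per gene. The defence list divided 36 in A and 20 in B. Its median was at percentile 9.97, within the bounds, but its share in A was at 99.465 (99.905 with 1 transcript per gene), outside them. Senescence proteases divided 2 and 10, the median at percentile 97.2 and the share in A at 1.83 (1.98), towards B. The 10 included all 6 subtilisin-like proteases, a cysteine proteinase, Glyma.17G254900.2, with 1236 in B and none in A, and a proteinase inhibitor, Glyma.14G038300.1, with 16366 against 18.7. The inhibitor matched the list's wording but is not a protease, and the split and percentiles were not recomputed without it. Jasmonate and storage proteins divided 3 and 10, at percentile 83.4. Vegetative storage protein B, Glyma.08G200100.1, a leaf store of nitrogen, had 13608 in B and 13.7 in A, 993-fold (555 to 1990). Of chlorophyll breakdown, STAY-GREEN, Glyma.17G132900.1, had 632 in B and none in A, and NYC1, Glyma.07G085700.2, had 349 in A and none in B, the list dividing 1 and 3. All 3 NAC factors had more reads in A, and WRKY factors divided 6 and 3 (percentile 8.70). Nitrogen remobilisation divided 12 and 11 (17.995), with all 6 allantoate-degrading enzyme transcripts in A, and cytosolic glutamine synthetase, Glyma.11G215500.2, at 2954 in B and 62.3 in A.

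The other lists at 95 days had a median and a share in A within percentiles 2.5 and 97.5, or had fewer than 5 members. In A and B they held 6 and 7 for flowering, 0 and 1 for light harvesting, 3 and 4 for carbon fixation, 2 and 3 for chlorophyll synthesis, 2 and 4 for autophagy, 7 and 8 for sugar, 11 and 14 for ethylene, 9 and 18 for abscisic acid, 10 and 8 for auxin, 1 and 1 for gibberellin, 11 and 22 for heat shock, 4 and 5 for oxidative stress, 14 and 15 for phenylpropanoids, 13 and 13 for cell wall, 1 and 2 for ribosomal proteins, 14 and 13 for cell division, 6 and 4 for guard cell, 0 and 3 for vascular tissue, 7 and 7 for seed proteins, 1 and 0 for nodule and root, and 3 and 1 for organelle and RNA quality. Over both ages, 5 of 43 list medians fell outside percentiles 2.5 to 97.5, and 2 of these 5 did so with 1 transcript per gene, the phenylpropanoid and the cell division lists at 50 days. The others were the clock list at 50 days and the cytokinin list at both ages, which share many transcripts. About 5% of random lists would fall outside these bounds, and whether 5 or 2 of 43 exceeds that was not tested. By the share in A, a statistic added after seeing the data, 9 of 43 fell outside, 4 of them with the median outside too, and 7 of the 9 did so with 1 transcript per gene.

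Independent lists would share about 99.4 transcripts if all tested ones were equally likely to be listed, an assumption that was not checked. The types' difference at both ages was compared over the 788 transcripts that were listed at both. Of these, 536 (68.0%, 64.6 to 71.3, exact binomial interval) lay on the same side at both ages, 317 in A and 219 in B, and 252 on opposite sides, 177 in A then B and 75 in B then A. Across these transcripts, which are not independent replicates, Pearson's r of the log2 ratios was 0.361 and Spearman's rho 0.338. For transcripts called at either age, 44 of 61 lay on the same side. Defence transcripts kept their side in 27 of 28 cases, 19 in A and 8 in B, whereas 15 of 19 clock transcripts were on opposite sides, 11 of them in A at 50 days and B at 95. Those 11 were isoforms of the genes Glyma.07G049400, Glyma.19G260400 and Glyma.03G261300, so the clock transcripts were not independent cases.

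**Figure D2:**
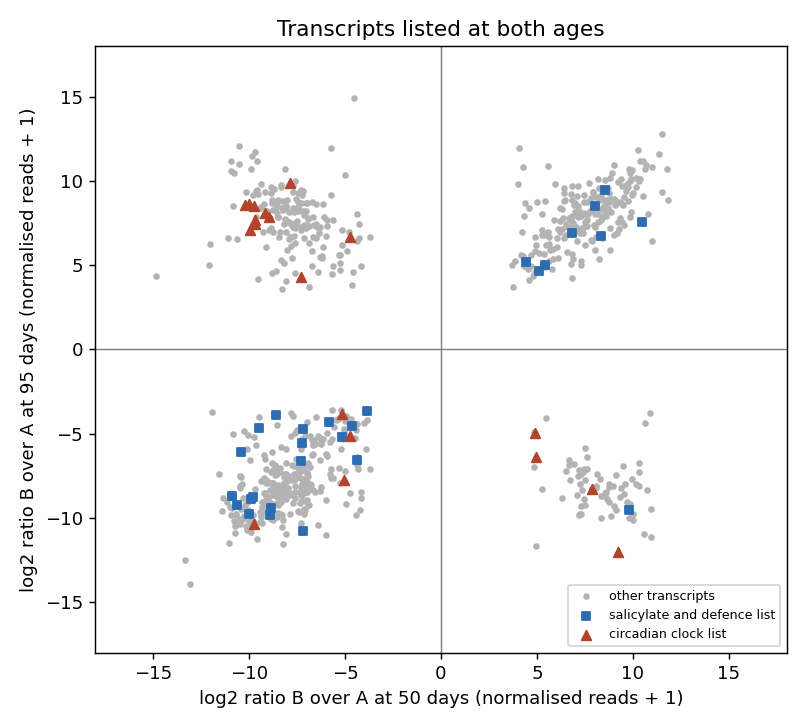
Log2 ratio of normalised reads plus 1, type B over type A, at 50 days (horizontal axis) and 95 days (vertical axis) for the 788 transcripts listed at both ages, 1 point per transcript and 1 library per type and age. Squares are the 28 defence transcripts, 27 of them in the lower left or upper right. Triangles are the 19 clock transcripts, 15 of them in the other corners, several of these being isoforms of one gene. The empty bands around 0 come from the listing of transcripts with an unadjusted p under 0.05.

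There were 8 transcripts called at both ages, where independent calls would share 0.0691, 5 on the same side and 3 on opposite sides. The 0.0691 takes every tested transcript as equally likely to be called. Called transcripts had mean levels of at least 309 at 50 days and 794 at 95 days, so the excess was not read as a result. In A at both ages were the proteasome subunit PSB7B, Glyma.14G014800.4 (at least 340-fold, then 568-fold), and the DUF3-like protein. In B at both were the calcium pump ACA10, Glyma.17G057800.3 (at least 551-fold, then 617-fold), SABRE-like Glyma.06G098300.4 (1084-fold, then 826-fold) and 1 isoform of the photorespiratory enzyme PGP1B, Glyma.18G244900.2 (1198-fold, then 1869-fold). Another PGP1B isoform, Glyma.18G244900.3, was at least 530-fold higher in A at 50 days and 1171-fold higher in B at 95 days. The Mediator subunit MED12, Glyma.18G232900.3, was at least 637-fold higher in B and then 604-fold higher in A, and DCAF1, Glyma.04G073900.3, at least 817-fold higher in B and then 674-fold higher in A. Another MED12 isoform, Glyma.18G232900.1, lay on the other side at 50 days. It had 2795 normalised reads in A and 16.9 in B, 165-fold (104 to 279).

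Change with age within a type could be followed only for these 788 transcripts, by size, on the values as deposited. It takes A and B as the same types at both ages, which nothing states. In A, 139 were at least 2-fold higher and 289 at least 2-fold lower at 95 days; in B, 261 were higher and 151 lower. With each type's values divided by their median, these splits were 445 and 206 in A and 172 and 593 in B. The deposited medians were 167 at 50 days and 64.5 at 95 in A, and 5.69 and 83.0 in B. They are medians of transcripts listed for differing, so dividing by them does not test the scaling of the libraries. That scaling is only inferred, and no direction with age was read from either version of the splits.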

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

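The results here were singled out because the types differed one way at 50 days and the opposite way at 95 days, with 1 library per type and age. None of these differences between ages was tested, and all tests of explanations in this part were chosen after the results were seen.

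Of the transcripts listed at both ages, 252 had more reads in A at one age and in B at the other. For named transcripts the move of the log2 fold of B over A from 50 to 95 days was computed with 0 reads set to the bound of 3. Of those called at both ages, PGP1B, Glyma.18G244900.3, moved from A at 50 days to B at 95 days by at least 19.2, and DCAF1, Glyma.04G073900.3, and MED12, Glyma.18G232900.3, moved from B to A by -19.1 and -18.6 or beyond. These moves are of single isoforms. At 50 days another MED12 isoform, Glyma.18G232900.1, lay in A, with 2795 normalised reads against 16.9, and another PGP1B isoform, Glyma.18G244900.2, lay in B. The other 4 named transcripts moved from A to B and were called at one age only. THIC, Glyma.18G065700.2, moved by at least 16.02, with an adjusted p of 1 at 50 days in the authors' deposited table, and the PRR95-like Glyma.07G049400.14 by at least 15.2, with 0.123 at 95 days. For the ABC transporter Glyma.08G070800.2 (17.7, adjusted p 1 at 95 days) and peamaclein, Glyma.06G044400.1 (16.4, adjusted p 0.515 at 50 days), the fold at 95 days entered as the observed ratio, so these 2 sizes are not lower bounds. The sizes do not rank the transcripts.

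Clock transcripts were on opposite sides in 15 of the 19 cases listed at both ages, 11 of them PRR5, PRR7 and PRR9-like transcripts with more reads in A at 50 days and in B at 95. Those 11 were isoforms of the genes Glyma.07G049400, Glyma.19G260400 and Glyma.03G261300, not independent cases. Reads moved between isoforms of one gene were not excluded. The summed listed reads of all 5 PRR genes listed at both ages changed sides, but only 1 of the 5 had listed isoforms on both sides at an age, so for the others the sum repeats the pattern, and unlisted isoforms are missing from it. An exchange of the A and B libraries at one age is argued against by the 68.0% of all transcripts listed at both ages that stayed on one side. A difference in daily phase between the libraries, from the hour of harvest or from the types' own clocks, may be behind it and stays open: the labels give no hour of harvest. Listed morning-phased output transcripts had more reads in A in 6 of 6 cases at 50 days and 3 of 4 at 95, a difference of 25 percentage points on too few transcripts to decide. A first version of that list, with LNK, chlorophyllide a oxygenase and FT transcripts picked with their values in view, gave 60 percentage points (40 of 40 against 6 of 15) and was set aside for that reason. The share of morning outputs in A was also no clear test of phase. LHY-like transcripts, of a morning-expressed factor, lay mainly in A at both ages (7 of 7, then 6 of 7), and outputs following them would stay there. REVEILLE 1-like transcripts lay in B at 50 days (2 of 2) and in A at 95 (6 of 6). TOC1-like ones did likewise (2 of 2, then 2 of 2).

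Isoforms of one gene lay on opposite sides at one age in 102 of 258 genes (39.5%) with at least 2 listed transcripts at 50 days. At 95 days this held for 145 of 280 (51.8%). Of all listed transcripts, 60.8% at 50 days and 46.7% at 95 days were in A. The rate for unrelated listed transcripts was not computed, so these shares are not shown to be raised. If the authors' counting had assigned one gene's reads to different isoforms in the 2 libraries, the gene's summed reads would differ little. The median absolute log2 ratio of summed listed reads was 0.813 at 50 days and 0.795 at 95 days, below all 1000 random pairings of opposite transcripts from different genes (median 1.30 and 1.42). That pairing was run first and favoured the explanation, but it ignores that isoforms of one gene have similar levels. Against pairings matched on level, added on seeing this, the medians were 0.793 and 0.869 and the observed values lay at percentiles 68.7 and 6. The bound that would exclude the explanation was also moved after these values were known, from the median to the 97.5th percentile of the matched pairings; at its first setting the 50-day value would have counted against it. As reported, the tables do not decide, and a difference in splicing between the types stays open and untested.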

How the results depend on the processing

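All but the choices said to be added were fixed before the data were examined. A minimum log2 ratio of 2 or none, the 75% of transcripts highest in mean level, centring on the median log2 ratio (-5.29 at 50 days, 4.52 at 95 days) and a pseudocount of 0.1 or 5 left every count of calls, overlap and list count they were run on within 1.5 times its value. None of them could have changed a call, so the counts say nothing about these choices. The smallest absolute log2 ratio of a called transcript was 9.24 at 50 and 10.63 at 95 days (3.95 and 6.11 after centring, 6.96 and 8.32 with a pseudocount of 5), and the smallest mean level 309 and 794, above the filter's 88.7 and 90.9. Requiring reads in both types left 7 of 77 calls in A and 1 of 35 in B at 50 days, and 0 of 19 and 5 of 18 at 95 days. At an adjusted p under 0.01, 3 and 0 were left at 50 days and 0 and 0 at 95 days; at an unadjusted p under 0.05 there were 1468 and 945, and 1154 and 1317. Of the clock list, leaving out members of more than one list left 2 of 4 calls at 50 days and 0 of 1 at 95 days, where calls in any list also went from 1 to 0. With 1 transcript per gene (added), 1 clock call was left at 50 days. Counting every listed transcript (added) gave 42 and 34 clock transcripts, 383 and 435 in any list, and 252 on opposite sides at both ages in place of 3; on the same side it gave 536 in place of 5. Judging lists by their share in A (added) put 7 at 50 days and 2 at 95 days outside the central 95% of random lists, in place of 4 and 1 by their median. The share of clock transcripts in A at 50 days, 88.1%, was 75% with 1 transcript per gene and 75% without PRR5, PRR7 and PRR9-like ones (both added). At 95 days, 50%, it was 88.9% without those and 87.5% without members of more than one list, since the PRR transcripts matched the cytokinin list too. Pearson's r was 0.497 over transcripts called at either age, in place of 0.361. Dividing by the median, which moved the median change by 1.37 (A) and -3.87 (B) on the log2 scale, gave 445 in place of 139 higher in A, 172 in place of 261 higher and 593 in place of 151 lower in B. Those medians are of transcripts listed for differing, so these counts do not test the scaling of the libraries. Where no construction shows it, the cause was not tested. Other normalizations were not run, as reads could be recovered only for listed transcripts, which were selected for differing, and with 1 library per type no replicate could be left out. No paired analysis was possible because the columns carry no replicate number and nothing states that A is the same type at both ages.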

Other observations

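The test in this part was chosen after its result was seen, and so were the transcripts named. Transcripts of LNK proteins, co-activators within the plant clock, were all on the A side at 50 days, 30 of 30 from 12 genes with 5 called, and divided 2 in A and 3 in B at 95 days. Both FT genes listed at both ages, florigens that promote flowering, had more reads in A at 50 days and in B at 95. Neither was called at either age, the authors' adjusted p at 50 days being 0.153 for Glyma.16G150700.1 and 0.108 for Glyma.16G044100.1. At 95 days the authors' adjusted p was 0.827 for Glyma.16G150700.1 and higher still for Glyma.16G044100.1. Glyma.16G150700.1, FT2a, had 191 normalised reads in A and none in B at 50 days, and 57.3 in A and 1364 in B at 95 days. Glyma.16G044100.1 had 266 in A and none in B, then 64.8 in A and 1103 in B. Chlorophyllide a oxygenase, Glyma.14G150600.1, went from 4267 in A and none in B to 8.72 in A and 752 in B, but another isoform, Glyma.14G150600.2, went the other way at 95 days, with 90.9 in A and 1.09 in B. Glyma.14G150600.1 was called at 50 days only, its authors' adjusted p at 95 days being 0.294. Cytosolic glutamine synthetase, Glyma.11G215500.2, had 6022 in A and 79.8 in B at 50 days, the opposite side from that at 95 days. The RuBisCO-associated protein Glyma.01G142400.1 had 47917 in B and 21.2 in A at 95 days, 2263-fold (1413 to 3885). Beta-amylase, Glyma.06G301500.1, a starch-degrading enzyme, had 34131 in B and 664 in A at that age.

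Transcripts of iron homeostasis were divided by function at 95 days. All 5 ferritin transcripts and both NEET proteins had more reads in A, whereas the iron-deficiency regulators ORG2 and ORG3, Glyma.03G130400.1 and Glyma.03G130600.1, had 1132 and 3016 in B and none in A. NRAMP3-like Glyma.17G165200.1, an exporter of vacuolar iron, had 91345 in B and 451 in A. A candidate explanation is a lower iron status in the leaf of B than of A. On the sides that this would predict lay 19 of 22 listed transcripts, 8 of 9 that deficiency raises and 11 of 13 that it lowers. The exceptions included an iron superoxide dismutase, Glyma.10G193500.1, with 2109 in B and 46.1 in A. At 50 days the same list held 7 transcripts, with all 5 that deficiency lowers in A and the 2 that it raises, both of one gene, divided 1 and 1. The gene list was written after the table had been read, so the count shows the pattern and does not test it, although the script first scored it as a fit; a test would need other plants.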
